A study of Mus musculus with 12 samples.

How the data were processed

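Liver RNA from 12 samples was hybridized as biotin-labelled cRNA to Illumina mouse bead arrays, 1 array per sample. The labels put 3 arrays in each of 4 groups by the compound injected, which were none, T3 for 3 days, XCT790 for 4 days, or XCT790 for 4 days with T3 on the last 3. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, and mice were kept on a 12-hour light cycle with free access to food.

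Per the file headers, the authors deposited a table of non-normalized probe intensity for each array, with a detection p-value for each probe. From its values, the deposited intensity was linear, always positive, not background-subtracted and not scaled between arrays. The deposited detection p-value took multiples of 1 small step between 0 and 1, as a rank among control beads of the same array would; how it was made is not given in the sources used here. The authors also deposited a matrix of processed intensity, which was linear and had the same quantiles on every array, with a median of 84.5. Quantile normalization of each array's own non-normalized signals gave the same values, and each column of the matrix matched its own array best. The submitters' processing notes name Partek 6.6, without saying at which step. The software of the scanner is not given in the sources used here.

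The non-normalized intensities were corrected for background with limma's normexp model, with the background estimated from the detection p-values and an offset of 16, then quantile-normalized between arrays and put on the log2 scale (limma 3.58.1 in R 4.3.3). Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept, 17218 of 45281. Probes were named through the platform annotation, which gave 1 symbol for 34885 probes, several for 18 and none for 10378. The Entrez numbers of 34807 named probes were found in the RefSeq gene table and 0 symbols needed an update. Of the kept probes 14446 had 1 symbol, and the probe with the highest mean log2 intensity stood for each gene, which left 9747 genes, 3374 of them with more than 1 kept probe. Where a called gene had other kept probes, all had its direction in 573 of 648 genes for T3 against control, 155 of 169 for XCT790 against control, 480 of 569 for T3 in mice given XCT790, 2 of 2 for XCT790 in mice given T3, and 18 of 21 for the interaction. Another probe was called in the opposite direction in 4 genes, Ahcy, Crybb3, Jak1 and Rps23rg1, all for T3 in mice given XCT790. The 2772 kept probes with no single symbol were tested apart.

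Group means were fitted over all 12 arrays with limma's lmFit, so that all groups share an estimate of the spread. Contrasts were tested with eBayes, two-sided, and p was adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05. The 5 contrasts were T3 against control, XCT790 against control, T3 in mice given XCT790, XCT790 in mice given T3, and the difference between both T3 responses (the interaction). Log2 fold changes are on the scale of the background-corrected values with offset 16, which understates changes of dim genes. A gene not above background on every array of a group was given a bound in place of a fold.

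In all, 42 lists of genes covering hormone response, mitochondria, autophagy, metabolism, stress, immunity, clock and liver cell types were fixed before the data were examined, as were the design, the settings to be tried and the rule for naming genes; 37 had at least 5 members tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a contrast. The rule named the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap, leaving out clone and predicted names, for each contrast of groups, and 5 in each direction for the interaction. It also named up to 4 members per list with the lowest p, and Esrra, Thra, Thrb, Ppargc1a, Thrsp, Dio1, Ulk1 and Dnm1l in every case.

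The procedure was tested on simulated data with the real design and 9747 genes. Noise was normal and independent between genes, and 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. The shares recovered depend on how many genes change, which is not known for the real data. For T3 against control, changes of 0.5, 1 and 2 on the log2 scale were recovered in 34.3%, 82.1% and 100% of genes, and 5.26% of calls were false. For XCT790 against control the shares were 41.8%, 89.6% and 97.0%, with 2.56% false, for T3 in mice given XCT790 20.9%, 83.6% and 98.5%, with 6.25% false, and for XCT790 in mice given T3 23.9%, 86.6% and 100%, with 3.45% false. For the interaction they were 5.97%, 67.2% and 90.9%, with 2.68% false.

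Settings tried in place of these were no background correction, median scaling, the deposited matrix, no filter and a stricter filter on dim probes (detection p under 0.01 on all 3 arrays of a group), the mean over the probes of a gene, each probe by itself, eBayes with trend and robust options, array quality weights, the replicate number as a block, only the arrays compared, other thresholds, and leaving out each array in turn. For the interaction, residuals of a limma fit with T3 and XCT790 as main effects were dealt again to the arrays. Unchanged groups were simulated from the residual variance of each gene, with each gene drawn independently, except where the residual covariance is named. Those draws, for glucocorticoid target genes and for differences between list medians, kept the residual covariance between the genes. Slides were not tested as a block because the files name none. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision of every value; the arrays measure RNA only.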

Results

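Liver RNA from 8-week-old male C57BL/6 mice was measured on 12 Illumina bead arrays in 4 groups of 3. The groups were controls, mice given T3 (triiodothyronine, the active thyroid hormone) for 3 days, mice given XCT790 for 4 days, and mice given XCT790 for 4 days with T3 on the last 3. XCT790 is an inverse agonist of ESRRA (estrogen-related receptor alpha), a nuclear receptor known for driving genes of mitochondrial energy metabolism. The design asks how ESRRA and thyroid hormone act together on liver genes, with the turnover of mitochondria as its stated subject. Compounds were injected into the abdomen every day, and the labels record no injection for the controls, so each comparison with control may also hold effects of injection and vehicle; whether controls were given vehicle is not said. The labels number the arrays of a group from 1 to 3 without saying that each came from a separate mouse, so p-values measure only the spread between these arrays, which may be technical.

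Each array held 45281 probes, of which 31.9% to 35.6% were detected on any one array. The summed intensity per array lay between 14568457 and 22343383 and the median probe intensity between 78.0 and 92.3. Signal level differed between groups. Before scaling, the median background-corrected log2 intensity of kept probes was 6.82 to 7.12 in controls and 6.93 to 7.04 with T3. It was 6.51 to 6.76 with both compounds. With XCT790 alone it was 6.64, 6.65 and 7.27 on arrays 1, 2 and 3, and array 3 also had the highest summed intensity. The number of arrays, 3 per group, limits the precision of every value. Over the 9747 genes tested, arrays of the same group correlated at 0.989 to 0.992 and arrays of different groups at 0.969 to 0.990. The first principal component held 44.5% of the variance and parted the 6 arrays with T3 (16.4 to 22.6) from the 6 without (-22.8 to -16.6). The second held 14.1% and parted the control arrays (10.1 to 15.6) from those with XCT790 alone (-19.3 to -9.27). It also parted arrays with T3 alone (4.52 to 9.88) from those with both compounds (-5.57 to -3.21), though by less.

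**Figure D1:**
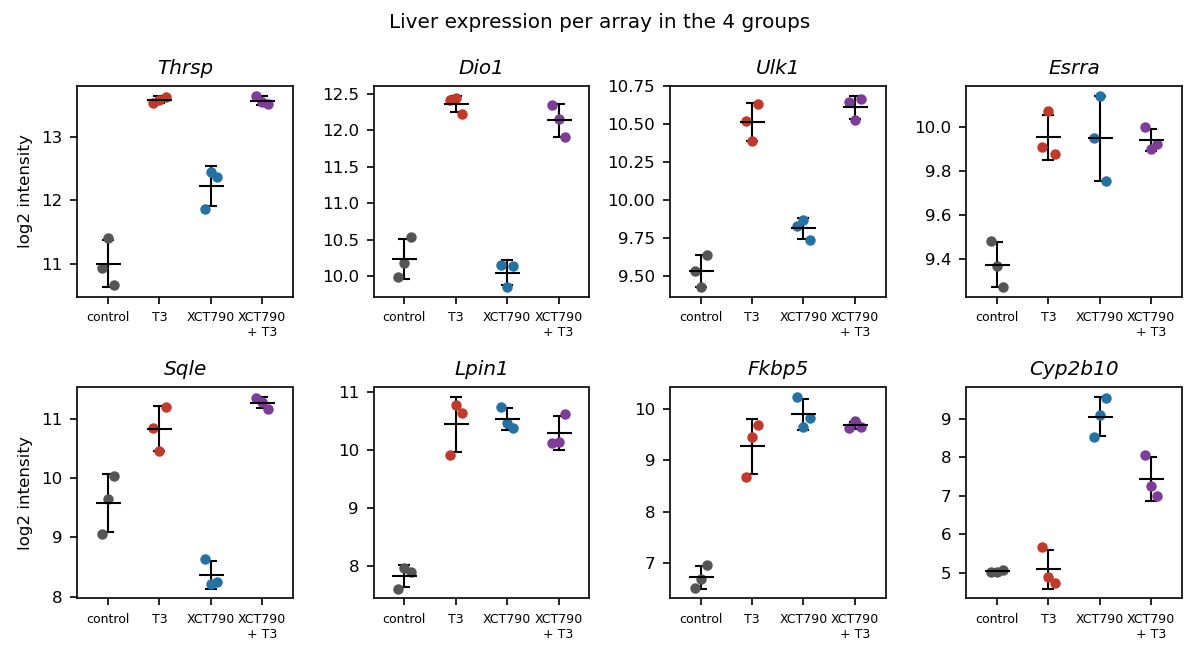
Normalized log2 intensity (y axis) of 8 genes on each array of the 4 groups (x axis); points are arrays and bars are the mean and SD of 3 arrays. Dio1 was higher with T3 by 2.13 without XCT790 and by 2.09 with it, whereas Fkbp5 was higher with T3 by 2.54 without XCT790 and differed by -0.21 with it.

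The comparison of T3 with control asked what the hormone did to the liver without XCT790. T3 raised known targets of the thyroid hormone receptor: Thrsp, a regulator of fatty acid synthesis, rose by 2.59 on the log2 scale (SE 0.18, adjusted p = 2.28e-06), and Dio1, the deiodinase that converts thyroxine to T3, rose by 2.13 (SE 0.16, adjusted p = 3.16e-06). Gpd2, the mitochondrial glycerophosphate dehydrogenase, rose by 1.26 (SE 0.10), and Pnpla3, a lipid droplet protein, by 4.71 (SE 0.25). In all, 1574 of 9747 genes changed, 706 higher and 868 lower, with an absolute log2 fold change of at least 1 in 308 of them (limma, Benjamini-Hochberg adjusted p under 0.05, two-sided). In 1565 of these the 3 T3 arrays lay entirely above or below the 3 control arrays. A call with 3 arrays per group nearly implies this, so the count adds no support. Over all genes the groups did not overlap in 34.8%, where chance gives 10% for any 1 gene. Genes move together, so a deviation shared by arrays of a group could raise that share.

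Among the genes that rose most with T3, Cyp17a1, a steroid hydroxylase and lyase, rose by 5.16 (SE 0.22, adjusted p = 6.11e-08), Pfkfb4, a kinase and phosphatase that sets glycolytic flux, by 3.65 (SE 0.27), and Mt1, the metal-binding metallothionein, by 3.53 (SE 0.52, adjusted p = 0.000665). Rnase2a, a secreted ribonuclease, was at least 29.0-fold higher and Sspo, a secreted glycoprotein, at least 8.98-fold higher. Neither was above background in controls, and such bounds set the mean of the brighter group against the lowest signal called detected on the arrays of the dimmer one. Crybb3, a lens crystallin, rose by 4.24 (SE 0.46). Lcn2, an iron-scavenging protein of inflammation, rose by 3.16 (SE 0.90, adjusted p = 0.0312), and this call was lost without any one of the control arrays or without T3 array 2 or 3 (adjusted p = 0.0658 to 0.122). Among the genes that fell most, Cyp4a12b, a fatty acid hydroxylase of male liver, fell by 4.24 (SE 0.22), Abcc3, an exporter of bile acid conjugates, fell by 3.48 (SE 0.13), and Cyp2c23, an arachidonic acid epoxygenase, fell by 3.12 (SE 0.14). Etnppl, which breaks down phosphoethanolamine, fell by 2.98 (SE 0.20). Serpina7, the thyroxine-binding globulin, was at least 9.35-fold lower and Hsd17b6, a hydroxysteroid dehydrogenase, at least 11.5-fold lower, both not above background with T3.

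Of 37 lists of genes fixed beforehand with at least 5 members tested, 11 passed camera, all upward. Camera, a two-sided test within limma, asks whether a list's genes moved further than other genes at a preset inter-gene correlation of 0.01. Only the list of thyroid hormone responsive genes also passed with an estimated correlation (adjusted p = 0.0192). In it 12 of 17 members rose and 0 fell over all genes, and adjusted over the list alone 12 rose and 1 fell (median log2 fold change 1.26, camera adjusted p = 1.51e-10). Fry, which tests whether a list's genes move on balance one way without comparing them with other genes, passed 19 lists.

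Lists of mitochondrial respiration genes had medians slightly above 0 with T3, and passed camera at the preset correlation but not at an estimated one. Of 34 subunits of complex I, 5 rose and 0 fell, both over all genes and adjusted over the list alone (median 0.16, camera adjusted p = 0.00167 and adjusted p = 0.394 with an estimated correlation). Examples were Ndufa5 (0.49, SE 0.09) and Ndufa1 (0.46, SE 0.09), whose calls ended with median scaling (adjusted p = 0.171 and 0.219). Complexes II to IV with cytochrome c had 3 of 20 members higher and 0 lower, by either adjustment (median 0.15, camera adjusted p = 0.0112, adjusted p = 0.394 with an estimated correlation), among them Cox7a1 (1.20, SE 0.21). In the tricarboxylic acid cycle 4 of 19 members rose and 1 fell, adjusted over the list alone likewise (median 0.21, camera adjusted p = 0.00977, adjusted p = 0.394 with an estimated correlation). Idh3a, a subunit of the NAD-dependent isocitrate dehydrogenase, rose by 1.68 (SE 0.10) and Idh2, the NADP-dependent enzyme, fell by 0.68 (SE 0.12). For ATP synthase 0 of 15 members passed limma's test, also adjusted over the list alone, and 3 at an unadjusted p under 0.05, with a median of 0.18, a camera adjusted p = 0.0228 and an adjusted p = 0.394 with an estimated correlation. With median scaling in place of quantile normalization the medians of these 4 lists stayed above 0, between 0.08 and 0.12, and none passed camera (adjusted p = 0.129, 0.122, 0.0747 and 0.276 in the order given). The ATP synthase call was also lost without T3 array 1 (adjusted p = 0.0897).

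The list of ESRRA, its relatives, coactivators and known targets had 4 of 20 members higher and 2 lower, by either adjustment (median 0.18, camera adjusted p = 0.0228, adjusted p = 0.434 with an estimated correlation). Its call was lost with median scaling (adjusted p = 0.0623) and without T3 array 1 (adjusted p = 0.0825). Esrrg, the gamma relative of ESRRA, rose by 1.72 (SE 0.22) and Acadm, a dehydrogenase of fatty acid oxidation, fell by 0.71 (SE 0.14). Esrra itself rose by 0.58 (SE 0.11, adjusted p = 0.00442), a call lost with median scaling (adjusted p = 0.0501). Ppargc1a, a coactivator of ESRRA, differed by 0.44 without passing (SE 0.20, adjusted p = 0.16).

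None of the lists of mitochondrial turnover passed camera for T3 against control, while each of the 37 lists passed fry's mixed test, which takes changes in either direction. Ulk1, a kinase that starts autophagy, rose by 0.98 (SE 0.10, adjusted p = 4.71e-05), and Foxo1, a transcription factor of autophagy and fasting genes, rose by 1.40 (SE 0.18). Sqstm1, the autophagy receptor p62, fell by 0.49 (SE 0.09). Of 34 autophagy and lysosome genes 5 rose and 3 fell, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.558). Of 18 mitophagy genes 2 rose and 2 fell, or 3 and 3 adjusted over the list alone, with a median of -0.04, a mean of 0.02 and a camera adjusted p = 0.984. Of 13 fission and fusion genes 1 rose and 1 fell by either adjustment (camera adjusted p = 0.558), and Dnm1l, the fission GTPase, differed by 0.07 (95% interval -0.16 to 0.30). In mitochondrial translation 0 of 33 members rose and 2 fell (camera adjusted p = 0.558), among them Mrpl14, a ribosomal protein, which fell by 0.58 (SE 0.09). In the biogenesis list 0 of 22 rose and 1 fell (camera adjusted p = 0.605), and both lists had these counts adjusted over the list alone too. Thra and Thrb, the genes of the thyroid hormone receptors, had 1 probe each, detected on too few arrays to be tested.

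Lipid genes moved in both directions. PPARA targets rose as a group, with 7 of 17 members higher and 0 lower, or 8 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 0.0066, adjusted p = 0.512 with an estimated correlation). Fgf21, a fasting hormone, rose by 2.14 (SE 0.37) and Plin5, a lipid droplet coat protein, by 1.29 (SE 0.17). The list's call was lost without T3 array 2 (adjusted p = 0.0794). Fatty acid and triglyceride synthesis had 7 of 21 members higher and 4 lower, or 7 and 6 adjusted over the list alone, with a median of -0.16, a mean of 0.34 and a camera adjusted p = 0.558. In it Lpin1, a phosphatidate phosphatase, rose by 2.62 (SE 0.22), whereas Srebf1, the transcription factor of lipogenesis, fell by 1.70 (SE 0.14). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 2.06 (SE 0.32), in a bile acid list with 5 of 17 members higher and 3 lower by either adjustment (camera adjusted p = 0.925). Cholesterol synthesis and uptake had 5 of 18 members higher and 1 lower, or 7 and 1 adjusted over the list alone (median 0.15, camera adjusted p = 0.0534), with Sqle, the squalene epoxidase, higher by 1.25 (SE 0.24). Fatty acid oxidation had 2 of 23 members higher and 2 lower by either adjustment (camera adjusted p = 0.558).

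Markers of liver macrophages rose with T3, with 9 of 12 higher and 0 lower, or 10 and 0 adjusted over the list alone (median 0.75, camera adjusted p = 8.64e-06, adjusted p = 0.434 with an estimated correlation). Timd4, a receptor of resident Kupffer cells, rose by 1.26 (SE 0.16) and Cd163, a haemoglobin scavenger receptor, by 1.42 (SE 0.25). Acute phase genes had 5 of 24 members higher and 0 lower, or 5 and 2 adjusted over the list alone (median 0.39, camera adjusted p = 0.0105, adjusted p = 0.689 with an estimated correlation), and the call was lost without T3 array 3 (adjusted p = 0.157). Saa4, a serum amyloid, rose by 1.29 (SE 0.26). Endothelial markers had a median of 0.26 with 0 of 15 past limma's test, also adjusted over the list alone, and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.0228, adjusted p = 0.434 with an estimated correlation). That call was lost with median scaling (adjusted p = 0.0574) and without control array 2 or 3 or T3 array 1 (adjusted p = 0.0615, 0.0731 and 0.109). Of 17 hepatocyte markers 1 rose and 1 fell by either adjustment (median -0.04, camera adjusted p = 0.652). The count of changed genes fell to 942 with median scaling, 389 higher and 553 lower, of which 920 were also called with quantile normalization.

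XCT790 without T3 asked which liver genes responded to the ESRRA inverse agonist when no hormone was given. Mt1 rose by 4.24 (SE 0.52, adjusted p = 0.00106), and Cyp2b10, the drug-metabolizing enzyme induced through the receptor CAR, was at least 14.8-fold higher than in controls, where it was not above background. Fkbp5, a cochaperone of steroid receptors, rose by 3.17 (SE 0.23, adjusted p = 6.11e-05), Lpin1 by 2.71 (SE 0.22) and Plin4, a lipid droplet coat protein, by 2.85 (SE 0.36). Spon2, a secreted matrix protein, fell by 2.04 (SE 0.21). In all, 433 of 9747 genes changed, 223 higher and 210 lower, 99 with an absolute log2 fold change of at least 1 (limma, adjusted p under 0.05, two-sided). In each of the 433 the groups did not overlap, which a call nearly implies. The share over all genes was 21.9%, where chance gives 10% for any 1 gene. The count was 269, 217 and 256 without control arrays 1, 2 and 3, 186 without XCT790 array 1, and 231 without XCT790 array 2. Median scaling called 235 genes, 98 higher and 137 lower, so that more fell than rose, with the median of all genes at -0.09.

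Other genes that rose were Acot3, a peroxisomal thioesterase (2.83, SE 0.46), Nrg4, a secreted growth factor of the EGF family (2.35, SE 0.27), and Zbtb16, a zinc finger transcription factor (2.22, SE 0.32). Aqp8, an aquaporin, fell by 2.01 (SE 0.33), Ddc, the aromatic amino acid decarboxylase, fell by 1.88 (SE 0.22), and Tiam2, a Rac exchange factor, fell by 1.44 (SE 0.26). Thrsp rose by 1.23 (SE 0.18, adjusted p = 0.00319), whereas Dio1 differed by -0.19 (adjusted p = 0.604). Esrra rose by 0.57 (SE 0.11, adjusted p = 0.0148), a call lost with median scaling (adjusted p = 0.115) and without control array 2 or 3 or XCT790 array 1 or 2 (adjusted p = 0.0538 to 0.0624). Ppargc1a lay near the threshold at 0.77 (SE 0.20, adjusted p = 0.0508) and passed without XCT790 array 3 (adjusted p = 0.016).

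Of the 37 lists 7 passed camera, 5 upward and 2 downward, and 8 passed fry, but none passed camera with an estimated correlation. Cholesterol synthesis and uptake had 0 of 18 members higher and 5 lower over all genes, and 15 lower adjusted over the list alone (median -0.61, camera adjusted p = 4.26e-09, adjusted p = 0.335 with an estimated correlation). Mvd, the mevalonate diphosphate decarboxylase, fell by 1.18 (SE 0.21) and Sc5d, a sterol desaturase, fell by 0.86 (SE 0.15). Sqle fell by 1.22 (SE 0.24, adjusted p = 0.0136), a call lost without control array 2 (adjusted p = 0.0552) or XCT790 array 2 (adjusted p = 0.0586). Interferon response genes fell as a group, 2 of 19 over all genes and 9 adjusted over the list alone, with 0 higher (median -0.43, camera adjusted p = 4.78e-07, adjusted p = 0.345 with an estimated correlation). Psmb9, an immunoproteasome subunit, fell by 1.04 (SE 0.15). Of 4 lymphocyte markers, too few for camera, limma called 0 over all genes, with 3 lower adjusted over the list alone and 3 at an unadjusted p under 0.05 (median -0.59).

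PPARA targets rose as a group, with 5 of 17 higher and 1 lower, or 9 and 1 adjusted over the list alone (median 0.48, camera adjusted p = 8.76e-05, adjusted p = 0.506 with an estimated correlation, fry adjusted p = 0.0745). Plin5 rose by 1.49 (SE 0.17). Targets of the xenobiotic receptors CAR and PXR had 5 of 19 members higher, 6 adjusted over the list alone, and 0 lower (median 0.20, camera adjusted p = 8.76e-05, adjusted p = 0.335 with an estimated correlation). Nr1i3, which encodes CAR, rose by 0.95 (SE 0.15) and Sult1d1, a sulfotransferase, by 1.04 (SE 0.12). Circadian clock genes had 5 of 15 higher and 1 lower, or 6 and 2 adjusted over the list alone (median 0.31, camera adjusted p = 0.0057, adjusted p = 0.259 with an estimated correlation). Usp2, a clock-controlled deubiquitinase, rose by 1.96 (SE 0.15), Per1, a repressor within the clock, by 1.07 (SE 0.16), and Nr1d1, the repressor REV-ERB alpha, fell by 1.48 (SE 0.23). Genes of gluconeogenesis and glycolysis had 2 of 17 higher, 4 adjusted over the list alone, and 0 lower (median 0.16, camera adjusted p = 0.0199, adjusted p = 0.259 with an estimated correlation), among them Pck1, which commits carbon to glucose synthesis (0.95, SE 0.16). The list's call was lost without XCT790 array 3 (adjusted p = 0.15).

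Genes of mitochondrial respiration showed no change with XCT790 alone that passed a test. Complex I had a median of -0.02 (camera adjusted p = 0.849), complexes II to IV of -0.05 (camera adjusted p = 0.534), ATP synthase of -0.04 (camera adjusted p = 0.679) and the tricarboxylic acid cycle of 0.0084, with a mean of -0.01 (camera adjusted p = 0.921). In these 4 lists limma called 0 members, also adjusted over the list alone, and at an unadjusted p under 0.05 they held 1, 0, 0 and 1, while 1748 of all genes passed that threshold. The list of ESRRA, its relatives and targets had 1 of 20 members higher and 1 lower, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.849). Of 34 autophagy genes 1 rose, Foxo1 (1.04, SE 0.18), and 1 fell (camera adjusted p = 0.928), and of 18 mitophagy genes 0 rose and 1 fell (camera adjusted p = 0.687), by either adjustment. Ulk1 differed by 0.28 without passing (SE 0.10, adjusted p = 0.15). Fry's mixed test, which takes changes in either direction, passed 23 of the 37 lists but none of the 4 respiration lists. It passed the ESRRA list (adjusted p = 0.00107), mitophagy (adjusted p = 5.64e-05) and autophagy (adjusted p = 3.12e-05). Macrophage markers had a median of -0.27 (camera adjusted p = 0.0874) and hepatocyte markers of -0.0023 (camera adjusted p = 0.849). Limma called 0 of 12 and 0 of 17 of them, also adjusted over the list alone, and 2 and 0 had an unadjusted p under 0.05.

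T3 in mice also given XCT790 asked what the hormone did in the presence of the ESRRA inverse agonist. Thyroid hormone targets rose again: Dio1 by 2.09 (SE 0.16, adjusted p = 3.78e-06), Gpd2 by 1.36 (SE 0.10), Pnpla3 by 4.59 (SE 0.25) and Thrsp by 1.35 (SE 0.18, adjusted p = 0.000429). Of the enzymes of cholesterol synthesis, Sqle rose by 2.91 (SE 0.24, adjusted p = 7.36e-06) and Mvd by 2.77 (SE 0.21, adjusted p = 3.78e-06). In all, 1481 of 9747 genes changed, 744 higher and 737 lower, 308 with an absolute log2 fold change of at least 1 (limma, adjusted p under 0.05, two-sided). In 1468 of them the groups did not overlap, which a call nearly implies. The share over all genes was 32.8%, where chance gives 10% for any 1 gene. Median scaling called 1254 genes with another split, 266 higher and 988 lower, and moved the median of all genes to -0.17, so that relative to all genes its changes lie higher by that amount. Without XCT790 array 2 the count was 971.

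Rnase2a rose by 6.09 (SE 0.39), Cux2, a transcription factor of female liver, by 4.34 (SE 0.25), Pfkfb4 by 4.35 (SE 0.27), Cyp17a1 by 4.24 (SE 0.22) and Ttbk1, a tau kinase, by 3.35 (SE 0.18). Sspo was at least 8.50-fold higher. Crybb3 rose by 4.31 (SE 0.46), although another of its probes was called in the opposite direction, as was the case in 4 genes of this comparison. Serpina7 fell by 3.41 (SE 0.21), Cyp4a12b fell by 3.21 (SE 0.22), Abcc3 fell by 3.07 (SE 0.13) and Abca8a, a lipid transporter, fell by 3.05 (SE 0.14). Krt23, a keratin, was at least 4.95-fold lower.

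Of the 37 lists 12 passed camera, 10 upward and 2 downward, and 24 passed fry. Only the thyroid hormone list also passed camera with an estimated correlation (adjusted p = 0.0409). It had 10 of 17 members higher and 0 lower, or 12 and 1 adjusted over the list alone (median 0.99, camera adjusted p = 1.34e-08). Cholesterol synthesis and uptake had 13 of 18 higher, 14 adjusted over the list alone, and 0 lower (median 1.18, camera adjusted p = 1.21e-13, adjusted p = 0.206 with an estimated correlation). Interferon response genes had 9 of 19 higher, 13 adjusted over the list alone, and 0 lower (median 0.62, camera adjusted p = 2.24e-08, adjusted p = 0.214 with an estimated correlation). Gbp3, a guanylate-binding protein, rose by 2.35 (SE 0.14) and Isg15, a ubiquitin-like modifier, by 1.07 (SE 0.16). Macrophage markers had 8 of 12 higher, 10 adjusted over the list alone, and 0 lower (median 0.81, camera adjusted p = 7.01e-06, adjusted p = 0.325 with an estimated correlation), among them Timd4 (0.86, SE 0.16) and Clec4f, a Kupffer cell lectin (0.93, SE 0.22). Cell cycle genes had 7 of 19 higher, 9 adjusted over the list alone, and 0 lower (median 0.56, camera adjusted p = 0.000498, adjusted p = 0.325 with an estimated correlation). Ccnd1, the cyclin of the entry into the cycle, rose by 2.07 (SE 0.39) and Cdc20, an activator of the anaphase-promoting complex, by 2.22 (SE 0.40).

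CAR and PXR targets fell as a group, with 2 of 19 higher and 11 lower, or 2 and 12 adjusted over the list alone (median -0.51, camera adjusted p = 0.000413, adjusted p = 0.241 with an estimated correlation). Cyp3a11, a drug-metabolizing enzyme, fell by 1.75 (SE 0.23) and Nr1i3 fell by 1.27 (SE 0.15), whereas Gstt1, a glutathione transferase, rose by 2.03 (SE 0.11). Gluconeogenesis and glycolysis passed camera downward, with 1 of 17 higher and 4 lower, or 2 and 6 adjusted over the list alone (median -0.28, camera adjusted p = 0.0331, adjusted p = 0.206 with an estimated correlation). Fbp1, the fructose bisphosphatase, fell by 0.74 (SE 0.14), and the list's call was lost without XCT790 array 3 (adjusted p = 0.0803). Of 23 fatty acid oxidation genes 0 rose and 7 fell, by either adjustment, with no call for the list (median -0.09, camera adjusted p = 0.0941).

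Complex I genes had 4 of 34 higher and 0 lower, by either adjustment (median 0.12, camera adjusted p = 0.0096, adjusted p = 0.241 with an estimated correlation), but with median scaling their median turned to -0.11, against -0.17 for all genes, and the call ended (adjusted p = 0.562). Complexes II to IV had 3 of 20 higher, 5 adjusted over the list alone, and 0 lower (median 0.20, camera adjusted p = 0.00177, adjusted p = 0.206 with an estimated correlation), and 0.0013 with median scaling (adjusted p = 0.0806). ATP synthase had 0 of 15 past limma's test, also adjusted over the list alone, and 5 at an unadjusted p under 0.05, with a median of 0.17 (camera adjusted p = 0.0263, adjusted p = 0.277 with an estimated correlation) that turned to -0.03 with median scaling (adjusted p = 0.297). Its call was also lost without XCT790 array 2 (adjusted p = 0.0704) or without array 1 of both compounds (adjusted p = 0.0579). Ndufa5 rose by 0.56 (SE 0.09) and Ndufa1 by 0.48 (SE 0.09), and both calls ended with median scaling (adjusted p = 0.214 and 0.375). Cox7a1 rose by 1.17 (SE 0.21) and Idh3a by 1.39 (SE 0.10). The tricarboxylic acid cycle had 3 of 19 higher and 1 lower (camera adjusted p = 0.126) and the ESRRA list 4 of 20 higher and 1 lower (camera adjusted p = 0.144), by either adjustment. Ulk1 rose by 0.80 (SE 0.10, adjusted p = 0.000249), while Esrra differed by -0.0072 (adjusted p = 0.977). Hepatocyte markers had a median of -0.0092 with 0 of 17 past limma's test, also adjusted over the list alone, and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.599).

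**Figure D2:**
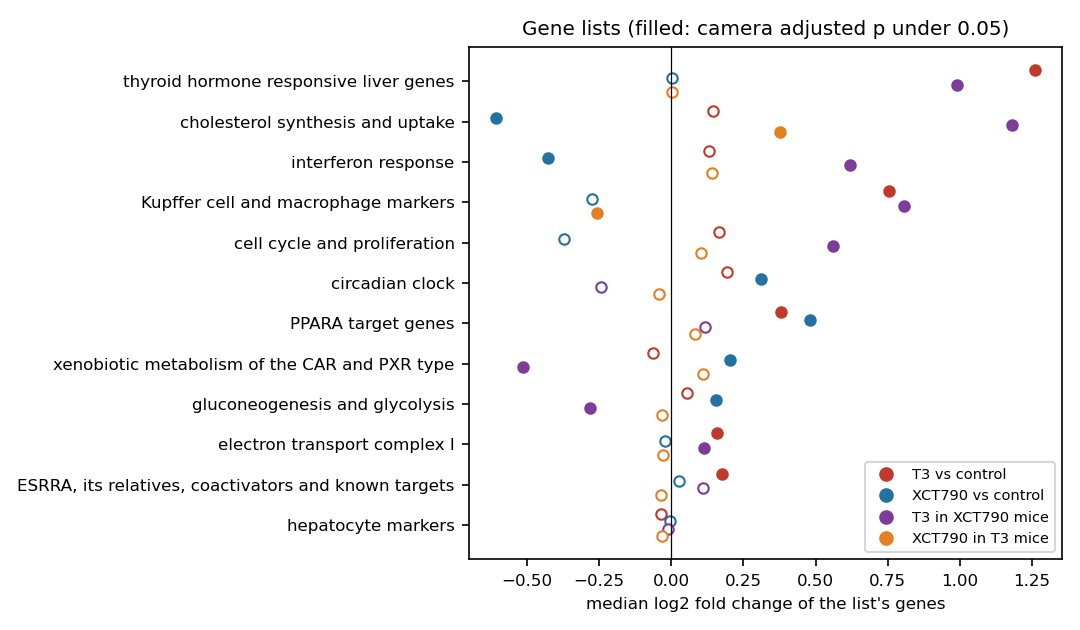
Median log2 fold change (x axis) of the genes of 12 lists (y axis) in 4 comparisons; filled points passed camera with a preset correlation at an adjusted p under 0.05 and open points did not. Cholesterol synthesis lay at -0.61 with XCT790 alone and at 1.18 with T3 in mice given XCT790. Complex I lay at 0.12 in the latter, which turned to -0.11 with median scaling, where the median of all genes was -0.17.

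XCT790 in mice given T3 asked what the compound did in a liver under thyroid hormone. Cyp2b10 rose by 2.35 (SE 0.31, adjusted p = 0.019), Cux2 by 2.23 (SE 0.25, adjusted p = 0.00616) and A1bg, a plasma glycoprotein of the immunoglobulin family, by 2.18 (SE 0.15, adjusted p = 3.8e-05). Mycl, a member of the MYC family, rose by 1.25 (SE 0.15) and Emilin1, a matrix glycoprotein, fell by 1.18 (SE 0.18, adjusted p = 0.0351). Limma called 9 of 9747 genes, 7 higher and 2 lower, with no overlap between the groups in any, while 1242 had an unadjusted p under 0.05. The groups did not overlap in 19.3% of all genes, where chance gives 10%. The remaining calls were Dlx1as, an antisense transcript at least 1.07-fold higher, Acnat2, an acyltransferase (0.66, SE 0.11), Grhl1, a transcription factor (0.62, SE 0.10), and Arsa, the lysosomal arylsulfatase (-0.82, SE 0.13). A1bg kept its call whichever array was left out, whereas Cux2 and Mycl lost theirs without array 1 of both compounds (adjusted p = 0.0509 for each). Cyp2b10 lost its call without control array 1 (adjusted p = 0.0524), T3 array 2 or 3 (adjusted p = 0.111 and 0.0914), or array 1 or 2 of both compounds (adjusted p = 0.0509 and 0.0587). The other 5 lost theirs without 6 or more of the 12 arrays, at adjusted p of up to 0.111 for Dlx1as and Emilin1, 0.189 for Acnat2 and Grhl1, and 0.181 for Arsa. The count was 3 without control array 1, 4 without control array 2, 5 without control array 3, 3 without T3 array 2, 5 without T3 array 3, 4 without XCT790 array 1, and 1 and 4 without arrays 1 and 2 of both compounds. Median scaling called 18 genes, 3 higher and 15 lower, with the median of all genes at -0.22.

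In T3-treated mice 2 of 37 lists passed camera for XCT790, and none passed fry in one direction or camera with an estimated correlation. Fry's mixed test passed 3, mitochondrial translation (adjusted p = 0.0106), CAR and PXR targets (adjusted p = 0.000399) and growth hormone and sex-biased genes (adjusted p = 2.51e-05). Cholesterol synthesis and uptake had 0 of 18 members past limma's test over all genes, 6 higher adjusted over the list alone and 9 at an unadjusted p under 0.05 (median 0.38, camera adjusted p = 4.69e-05, adjusted p = 0.924 with an estimated correlation, fry adjusted p = 0.599). Macrophage markers had 0 of 12 past it over all genes, 1 lower adjusted over the list alone and 1 at an unadjusted p under 0.05 (median -0.26, camera adjusted p = 0.024, adjusted p = 0.924 with an estimated correlation, fry adjusted p = 0.599). The second call was lost without T3 array 3 (adjusted p = 0.12), XCT790 array 3 (adjusted p = 0.0649) or array 2 of both compounds (adjusted p = 0.468). Complex I had a median of -0.03 (camera adjusted p = 0.352), the tricarboxylic acid cycle of -0.08 (camera adjusted p = 0.229) and the autophagy list of -0.04 (camera adjusted p = 0.623). Limma called 0 members of these 3 lists, also adjusted over the list alone, and 3, 2 and 1 had an unadjusted p under 0.05. Esrra differed by -0.01 (adjusted p = 0.981).

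The difference between both T3 responses asked whether XCT790 altered what the hormone did. Lpin1 rose with T3 by 2.62 without XCT790 and differed by -0.24 with it, an interaction of -2.86 (SE 0.31, adjusted p = 0.00422). Fkbp5 behaved likewise (2.54 and -0.21, interaction -2.76, SE 0.33, adjusted p = 0.00596), and Usp2 rose by 1.14 without XCT790 and fell by 0.75 with it (interaction -1.88, SE 0.21, adjusted p = 0.00422). Arhgap26 and Slc1a4, a neutral amino acid transporter, had interactions of 1.99 (SE 0.28, adjusted p = 0.0121) and 1.98 (SE 0.28, adjusted p = 0.0133). In all, limma called 45 genes, 18 with a higher T3 response under XCT790 and 27 with a lower one, and 1181 had an unadjusted p under 0.05. Of the 45, 40 had changed with XCT790 alone, 38 with T3 alone and 34 with each, 31 of the 34 in the same direction, and 3 were also called for XCT790 in T3-treated mice. Both effects share their controls, and the 45 strongest interactions of simulated unchanged groups had them in the same direction in 44.8 genes on average (100 simulations), against 38 here, called or not. In 40 the absolute effect of XCT790 was larger without T3 than with it.

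Other genes with a lower T3 response under XCT790 were Plin5 (-1.65, SE 0.24, adjusted p = 0.0156), Plin4 (-2.77, SE 0.50, adjusted p = 0.0382), Eif4ebp3, a translation repressor (-2.26, SE 0.35, adjusted p = 0.0176), Tom1l2, a trafficking adaptor (-2.08, SE 0.34), and Sult1d1 (-0.88, SE 0.16). Those with a higher response were A1bg (2.23, SE 0.20, adjusted p = 0.00143), Tubb2b, a tubulin (2.12, SE 0.38), Cux2 (1.99, SE 0.35), Mvd (1.90, SE 0.29, adjusted p = 0.0178) and Cyp51, the lanosterol demethylase (1.12, SE 0.21). Controls were not above background for Tom1l2, Cux2 and A1bg, nor mice given XCT790 alone for A1bg, so the sizes of these 3 are not exact. Lpin1, Fkbp5, Usp2, Plin5, A1bg, Arhgap26 and Slc1a4 kept their calls whichever array was left out. Leaving out 1 array ended the calls of Plin4, Tubb2b, Cux2, Cyp51 and Sult1d1 for 9 or more of the arrays (adjusted p of up to 0.0986, 0.0986, 0.0986, 0.0977 and 0.111). It ended that of Tom1l2 for any control array or arrays 1 and 2 of both compounds (up to 0.0702), that of Eif4ebp3 for XCT790 array 1 or arrays 1 and 2 of both compounds (up to 0.0588), and that of Mvd for control arrays 2 and 3 or arrays 1 and 2 of both compounds (up to 0.0588). The count of 45 was 22, 23 and 22 without control arrays 1, 2 and 3, 99, 19 and 22 without the T3 arrays in the same order, 21, 29 and 25 without the XCT790 arrays, and 18 and 17 without arrays 1 and 2 of both compounds. Median scaling called 43 genes, 28 of them among the 45, 8 higher and 35 lower, with the median of all genes at -0.13, and ended the calls of Cux2, Cyp51 and Sult1d1 (adjusted p = 0.0786, 0.177 and 0.151).

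Of the 37 lists 8 passed camera for the interaction, 3 upward and 5 downward, and 4 passed fry, but none passed camera with an estimated correlation. Cholesterol synthesis and uptake had 2 of 18 members higher over all genes and 15 adjusted over the list alone, with 0 lower (median 1.04, camera adjusted p = 6.02e-15, adjusted p = 0.222 with an estimated correlation). Interferon response genes had 0 of 19 past limma's test over all genes, with 10 higher adjusted over the list alone and 10 at an unadjusted p under 0.05 (median 0.52, camera adjusted p = 9.71e-09, adjusted p = 0.282 with an estimated correlation, fry adjusted p = 0.0544). Clock genes had 1 of 15 lower, Usp2, and adjusted over the list alone 1 higher and 6 lower (median -0.47, camera adjusted p = 0.00213, adjusted p = 0.222 with an estimated correlation). PPARA targets had 1 of 17 lower by either adjustment (median -0.30, camera adjusted p = 0.00144, adjusted p = 0.64 with an estimated correlation), a call lost without T3 array 2 (adjusted p = 0.198). CAR and PXR targets had 1 of 19 lower, 4 adjusted over the list alone (median -0.37, camera adjusted p = 0.0138, adjusted p = 0.593 with an estimated correlation), a call lost without T3 array 1 (adjusted p = 0.166), XCT790 array 3 (adjusted p = 0.0851) or array 3 of both compounds (adjusted p = 0.0731).

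No mitochondrial list passed camera for the interaction, while fry's mixed test passed 18 of the 37 lists, fission and fusion (adjusted p = 0.0418) and autophagy (adjusted p = 0.012) among them. Median interactions were -0.02 for complex I (camera adjusted p = 0.572), 0.03 for complexes II to IV (camera adjusted p = 0.75), -0.08 for the tricarboxylic acid cycle (camera adjusted p = 0.255), -0.22 for fission and fusion (camera adjusted p = 0.268), -0.02 for mitophagy (camera adjusted p = 0.681) and -0.02 for the ESRRA list (camera adjusted p = 0.316). Limma called 0 members of these lists, also adjusted over the list alone, and 1, 1, 1, 1, 2 and 2 had an unadjusted p under 0.05. The interaction of Ulk1 was -0.18 (95% interval -0.49 to 0.12), that of Dio1 -0.04 (-0.53 to 0.45), that of Esrra -0.58 (-0.93 to -0.24, adjusted p = 0.14) and that of Dnm1l 0.07 (-0.25 to 0.40). Thrsp came near the threshold at -1.24 (95% interval -1.80 to -0.67, adjusted p = 0.0596) and passed it without control array 2 (adjusted p = 0.0289) or XCT790 array 1 (adjusted p = 0.0458). In simulated data of the same design an interaction of 1 on the log2 scale was called in 67.2% of genes and one of 0.5 in 5.97%. These shares hold for independent genes with 67 changed by each amount, and can be lower where fewer genes change.

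Across the 9747 genes the log2 fold changes of T3 without and with XCT790, which share no arrays, correlated at a Pearson r of 0.692; genes are not independent replicates. The 1574 and 1481 calls had 802 genes in common, of which 789 moved the same way, 379 up and 410 down, where independent lists would share 53.9 and 65.6. Of all 1574 genes called without XCT790, 90.1% had the same direction with it, with a slope of 0.722. In the reverse, 91.3% of the 1481 genes called with XCT790 had the same direction without it, with a slope of 0.785. Choosing genes by their call in one comparison lowers such slopes, so neither measures a weaker response under XCT790. The effects of XCT790 without and with T3 correlated at 0.224. T3 and XCT790, each against the same controls, correlated at 0.367, where unchanged groups against those controls gave 0.501 in 100 simulations, while the covariance was 0.0504 against a simulated 0.0139. They had 197 calls in common in the same direction, 104 up and 93 down, where independent lists would share 16.2 and 18.7; part of that excess may come from the shared controls.

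**Figure D3:**
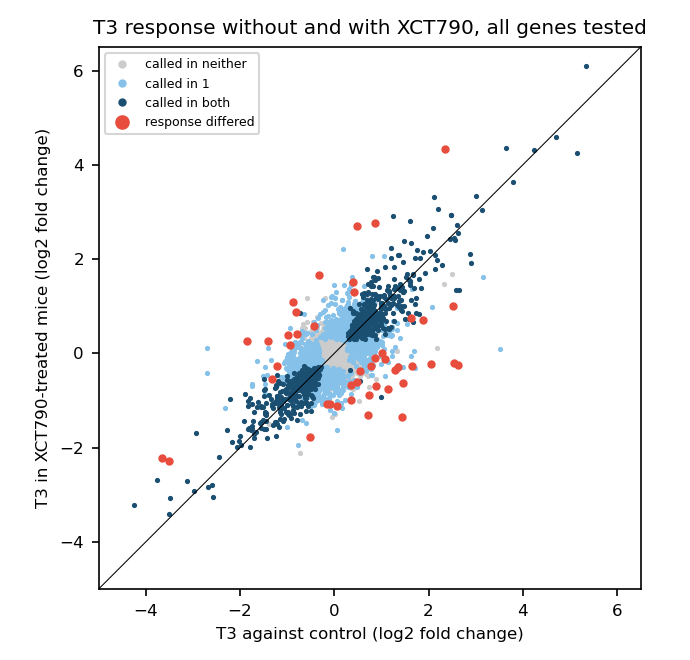
Log2 fold change of T3 without XCT790 (x axis) and with XCT790 (y axis) for each of 9747 genes; grey points were called in neither, light blue in 1 and dark blue in both, red points are the 45 genes whose response differed, and the line marks equal responses. The points follow the line (Pearson r 0.692), and red points lie on either side of it, 18 above and 27 below.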

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

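The tests of injection and handling, of scaling, of the share of hepatocytes, of the position of the controls and of residuals dealt again to the arrays were chosen only after the results were seen, whereas those of single arrays and of other groupings of the arrays were chosen before. Groups of 3 were not tested for outliers. The results here stand apart because the T3 response differed between mice without and with XCT790 by limma's test of that difference, or because they come from probes without a gene name.

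The T3 response differed in 45 genes. In 40 of them XCT790 had a larger effect without T3 than with it, against 22.6 on average and 32 at most among the 45 strongest interactions in each of 100 simulations of unchanged groups. In 22 the controls lay further from the nearest injected group than the injected groups lay from each other, against 2.05 on average and 6 at most. The other genes took other forms: mice given both compounds lay apart in A1bg, and mice given XCT790 alone in Arhgap26. The simulations drew each gene independently and with no effect of either compound. Real genes move together, so a deviation shared by the arrays of a group could raise such counts. The highest simulated counts may therefore lie too low to serve as limits.

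A single control array as the cause of the 45 interactions was argued against by their median ratio without 1 control array to that with all, which was never below 0.989, and scaling by a ratio of 1.08 with median scaling. Injection or handling may account for controls lying apart: 38 glucocorticoid target genes outside the 45 had medians of 0.64, 0.451 and 0.47 with T3, XCT790 and both against control (18, 14 and 15 higher, 0, 0 and 1 lower, camera p = 0.0273, 0.00698 and 0.0278 with an estimated correlation). These 3 comparisons share their controls and are not independent: unchanged groups simulated with the residual covariance of the 38 genes had all 3 medians above 0 in 2346 of 10000 draws, and all 3 at 0.451 or more in 0. The 15 genes of the 38 that stand in none of the fixed lists had medians of 0.38, 0.32 and 0.28. Genes named before for their changes were not taken out of these 15, so they are not a set of unseen genes. Among injected mice the 38 had medians of -0.04 with T3, which raised 5 and lowered 3 so that this median does not show them unchanged, and 0.01 with XCT790. The labels record no injection for controls and do not say whether vehicle was given. Injection, a shared effect of both compounds and an interplay between ESRRA and thyroid hormone thus stay open, the last 2 as untested. A shared effect of both compounds could also put these genes above controls in all 3 groups. Their medians therefore do not tell it from injection.

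Genes with a lower T3 response under XCT790 were Lpin1 (-2.86), Plin4 (-2.77), Fkbp5 (-2.76), Eif4ebp3 (-2.26), Tom1l2 (-2.08), Usp2 (-1.88), Plin5 (-1.65) and Sult1d1 (-0.88). Genes with a higher response were A1bg (2.23), Tubb2b (2.12), Arhgap26 (1.99), Cux2 (1.99), Slc1a4 (1.98), Mvd (1.90) and Cyp51 (1.12). The calls of Plin4, Eif4ebp3, Tom1l2, Sult1d1, Tubb2b, Cux2, Mvd and Cyp51 were lost without some arrays, at the adjusted p given with each in the comparison of both responses.

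Cholesterol synthesis and uptake genes differed in their T3 response by a median of 1.04, with a median of -0.61 for XCT790 without T3 and 0.38 with it. Scaling between arrays was argued against by a median interaction of 0.876 with median scaling, where all genes had -0.13. A single array was argued against by medians of no less than 0.913 (without array 1 of both compounds). A smaller share of hepatocytes with XCT790 was argued against by hepatocyte markers, whose median of -0.00229 lay 0.60 above that of the cholesterol list (permutation of genes between the lists, 100000 draws, two-sided p = 4e-05; as large in 0 of 10000 draws of unchanged groups with the residual covariance of these genes). An interplay of both compounds on sterol synthesis, injection, and a difference in feeding between groups may each stay as open explanations, untested, and the list's call did not hold with an estimated correlation (adjusted p = 0.222).

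Interferon response genes differed by a median of 0.52, with an adjusted p of 0.282 with an estimated correlation. Clock genes differed by -0.47 (adjusted p = 0.222 with an estimated correlation). PPARA targets differed by -0.30 (adjusted p = 0.64 with an estimated correlation, and 0.198 without T3 array 2). CAR and PXR targets differed by -0.37 (adjusted p = 0.593 with an estimated correlation), a call lost without T3 array 1, XCT790 array 3 or array 3 of both compounds (adjusted p = 0.166, 0.0851 and 0.0731). Gluconeogenesis and glycolysis differed by -0.0416 with 0 of 17 members past limma's test, 3 lower adjusted over the list alone and 5 at an unadjusted p under 0.05 (camera adjusted p = 0.0365, 0.222 with an estimated correlation), a call lost without control array 1, T3 array 1 or 3, XCT790 array 3 or array 3 of both compounds (adjusted p = 0.052, 0.0813, 0.05, 0.16 and 0.0731). Cell cycle genes differed by 0.43 with 0 of 19 past limma's test, 3 higher and 1 lower adjusted over the list alone and 7 at an unadjusted p under 0.05 (camera adjusted p = 0.0395, 0.64 with an estimated correlation), a call lost without control array 1 or 3, T3 array 2 or 3, XCT790 array 2 or array 3 of both compounds (adjusted p = 0.052, 0.0781, 0.126, 0.121, 0.117 and 0.239). Amino acid catabolism differed by -0.0892 with 0 of 22 past limma's test, 3 lower adjusted over the list alone and 6 at an unadjusted p under 0.05 (camera adjusted p = 0.0469, 0.553 with an estimated correlation). Its call was lost with median scaling (adjusted p = 0.15) and without control array 1 or 3, T3 array 1 or 3, XCT790 array 2 or 3, or array 3 of both compounds (adjusted p = 0.0867, 0.0781, 0.166, 0.0858, 0.06, 0.127 and 0.239). Fry did not pass PPARA targets, CAR and PXR targets, interferon response, cell cycle or amino acid catabolism (adjusted p = 0.361, 0.329, 0.0544, 0.375 and 0.102).

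Among 2772 kept probes without a single gene name, 253 changed with T3 against control (119 higher, 134 lower), 68 with XCT790 against control (45 and 23) and 244 with T3 in mice given XCT790 (113 and 131). Limma called 18 of them for the interaction.

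The 6 arrays of a pair of groups make 10 splits into 3 and 3, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many genes in each pair of groups. The real counts were 1574, 433, 1481 and 9 for T3 against control, XCT790 against control, T3 in mice given XCT790 and XCT790 in mice given T3, and the highest other splits gave 0, 3, 0 and 0. Each other split puts arrays of both groups together, which mixes the real difference into the spread within groups. Low counts there are largely set in advance, so no conclusion was drawn from them. For the interaction, 3 of 100 draws of the 12 arrays into 4 groups, the real one included, called 45 genes or more. Such draws mix the T3 effect into the spread within groups, so their share was not used. With the residuals of a fit of both main effects dealt again to the arrays, 1 of 100 draws, the real one, called 45 genes or more, and the highest other called 1. These residuals still hold the interaction, which such draws mix into the spread within groups, so low counts there are partly set in advance. Chance is not excluded by this share, also because the spread between arrays may be technical. The highest other draws into 4 groups called 2505 and 160 genes, which points to a structure of the samples. The draw with 2505 put all 6 arrays with T3 on one side of the contrast, so that it measured T3 itself. That with 160 put 5 there, as did another that called 0, and its cause was not tested.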

How the results depend on the processing

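No tests in this part were chosen after a result was seen, and where a cause is not named it was not tested. For counts of genes, counts of lists and the correlation of both T3 responses, 163 values stayed near the value reported and 67 did not. Near meant within 1.5 times for counts and within a fixed distance for the correlation. Of the values for single genes and lists, 6273 kept their side of the threshold, 755 lost it, 13 gained it and 0 turned. Turning meant the opposite sign for a called gene or the opposite camera direction for a list, so a list's median could still cross 0. Signal over background limits what could be tested, since no more than 35.6% of probes were detected on an array. The files name no slides, so slides were not run as a block, and a fit on the compared arrays alone does not exist for the interaction.

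Median scaling called 942 genes for T3 against control, 235 for XCT790 against control and 18 for XCT790 in mice given T3 (5 of the 9), and passed 6 lists for T3 against control and 4 for XCT790 in mice given T3. Without background correction 18 genes were called for XCT790 in mice given T3 (7 of the 9) and 142 for the interaction (44 of the 45), with the deposited matrix 17 (7) and 141 (44), and with trend and robust options 36 (7) and 145 (44). The interaction had 27 genes without a filter, where more genes are tested, 91 with the strict filter and 80 with array weights. Requiring an absolute log2 fold change of 1 left 308, 99, 308 and 5 genes in the comparisons of groups, and an adjusted p under 0.1 gave 764 for XCT790 against control, 19 for XCT790 in mice given T3 and 129 for the interaction. With only the arrays compared, which leaves fewer residual degrees of freedom, 250 genes were called for XCT790 against control and 1 for XCT790 in mice given T3.

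Camera with an estimated correlation passed 1, 0, 1, 0 and 0 lists in the 5 contrasts, in place of 11, 7, 12, 2 and 8, and fry passed 19 for T3 against control, 24 for T3 in mice given XCT790, 0 for XCT790 in mice given T3 and 4 for the interaction. The correlation of both T3 responses was 0.728 without background correction, 0.696 with median scaling, 0.724 with the deposited matrix, 0.646 without a filter and 0.659 to 0.704 with 1 array left out.

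With 1 array left out, T3 against control called 1148 to 1616 genes and XCT790 against control 186 to 419, with 269, 217 and 256 without control arrays 1 to 3 and 186 and 231 without XCT790 arrays 1 and 2. T3 in mice given XCT790 called 971 to 1458, the lowest without XCT790 array 2. XCT790 in mice given T3 called 1 to 9, with 3, 4 and 5 without control arrays 1 to 3, 3 and 5 without T3 arrays 2 and 3, 4 without XCT790 array 1, and 1 and 4 without arrays 1 and 2 of both compounds. The interaction called 17 to 99, with 22, 23 and 22 without control arrays 1 to 3, 99, 19 and 22 without the T3 arrays, 21, 29 and 25 without the XCT790 arrays, and 18 and 17 without arrays 1 and 2 of both compounds. Lists past camera were 10 to 13, 6 to 9, 11 to 12, 1 to 4 and 4 to 8 in the 5 contrasts. For XCT790 in mice given T3 there were 4 without T3 array 1 and 1 without T3 array 3, XCT790 array 3 or array 2 of both compounds, and for the interaction 5 without control array 1, T3 array 3 or XCT790 array 3 and 4 without array 3 of both compounds.

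Samples of different groups share only a replicate number. With that number as a block the 5 contrasts called 1529, 351, 1391, 3 and 25 genes, of which 1434, 328, 1295, 3 and 21 were called without it. Of the 118, 58, 112, 9 and 15 genes named and called, the block ended 4, 8, 6, 6 and 5 calls, and it ended that of amino acid catabolism for the interaction (adjusted p = 0.0539). The calls ended were those of Acnat2, Arsa, Cyp2b10, Dlx1as, Emilin1 and Grhl1 for XCT790 in mice given T3. For the interaction they were those of Cux2, Cyp51, Plin4, Sult1d1 and Tubb2b. Deviations of same-numbered arrays from their group means correlated at -0.131 to 0.131, with 2 of 18 pairs over 0.1, and 4 of 12 arrays correlated best with one of their own number.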

Other observations

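The tests of macrophage, endothelial and sex-biased genes in this part were chosen only after the results were seen, whereas the lists in the paragraphs before them were fixed before.

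Genes of the unfolded protein and integrated stress response had 7 of 22 members higher and 1 lower with T3 against control, by either adjustment (camera adjusted p = 0.0534). Creld2, a chaperone of the endoplasmic reticulum, rose by 1.62 (SE 0.20), whereas Trib3, a pseudokinase induced by stress, fell by 1.75 (SE 0.29). In mice given XCT790, T3 raised 4 of 22 and lowered 0 by either adjustment, and the list passed camera (median 0.25, camera adjusted p = 0.0384, adjusted p = 0.407 with an estimated correlation). That call was lost without control array 2, XCT790 array 3, or array 2 or 3 of both compounds (adjusted p = 0.0524, 0.0697, 0.0554 and 0.0578). Amino acid catabolism and the urea cycle had 5 of 22 members higher and 4 lower with T3 by either adjustment (median -0.08, mean -0.05, camera upward at an adjusted p = 0.984), with Prodh, the proline dehydrogenase, higher by 0.87 (SE 0.10) and Oat, the ornithine aminotransferase, lower (-1.74, SE 0.19). With XCT790 alone 4 rose and 0 fell, or 4 and 1 adjusted over the list alone (median 0.08, camera adjusted p = 0.0233, adjusted p = 0.401 with an estimated correlation), a call lost without control array 1 (adjusted p = 0.0946) or XCT790 array 3 (adjusted p = 0.0911). Gpt2, an alanine aminotransferase, rose by 0.69 (SE 0.09). Antioxidant genes under NRF2 had 2 of 20 higher and 4 lower with T3, or 2 and 5 adjusted over the list alone, with a median of -0.14, a mean of 0.10 and a camera adjusted p = 0.558.

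Exocrine pancreas markers passed camera for T3 against control, with 3 of 5 higher and 0 lower by either adjustment (median 0.34, camera adjusted p = 0.0228, adjusted p = 0.394 with an estimated correlation), a call lost without control array 3 (adjusted p = 0.0625). In mice given XCT790 they had 2 of 5 higher and 0 lower by either adjustment (median 0.19, camera adjusted p = 0.0123, adjusted p = 0.206 with an estimated correlation). Cela2a, an elastase, rose by 2.20 (SE 0.27) without and 3.07 (SE 0.27) with XCT790. Tff3, a trefoil peptide that stands among the cholangiocyte markers, rose by 3.12 (SE 0.35) and 3.04 (SE 0.35), in a list with 4 members tested. Among nuclear receptors 5 of 22 rose and 6 fell with T3, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.948), with Ppard, a fatty acid receptor, higher by 1.41 (SE 0.13) and Pparg, the receptor of fat storage, lower (-1.46, SE 0.14). Pericentral markers had 1 of 12 higher and 3 lower by either adjustment (camera adjusted p = 0.159, fry adjusted p = 0.00904), and periportal markers 3 of 9 higher and 3 lower by either adjustment, with a median of 0.02, a mean of -0.56 and adjusted p = 0.558 by camera and 0.00187 by fry. Cyp1a2, a pericentral cytochrome, fell by 1.47 (SE 0.14) without and by 1.24 (SE 0.14) with XCT790. Cdh1, the periportal cadherin, fell by 1.32 (SE 0.15) with XCT790 alone and rose by 1.02 (SE 0.15) with T3 in mice given XCT790.

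Macrophage markers were higher with T3 in both backgrounds, with medians of 0.75 and 0.81. A lower share of hepatocytes as the whole cause, which would raise the markers of other cells alike, was argued against by endothelial markers, whose medians lay 0.50 and 0.76 below those of macrophages (permutation of genes between the lists, 100000 draws, two-sided p = 0.00554 and 2e-05; as large in 101 and 0 of 10000 draws of unchanged groups with the residual covariance of these genes). Endothelial markers themselves had medians of 0.26 (camera adjusted p = 0.0228, fry adjusted p = 0.0303) and 0.05, and stellate markers 0.16 (fry adjusted p = 0.0387) and 0.10, so such a share as part of the change stays open. Scaling between arrays was argued against by medians of 0.697 and 0.58 with median scaling. More macrophages in the liver and more of these transcripts per macrophage may each be a candidate explanation, and bulk RNA does not separate them; the call did not hold with an estimated correlation (adjusted p = 0.434 and 0.325).

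A hypothesis of a shift of the male liver toward female-biased expression was tested on lists of genes known to differ between male and female mouse liver. With T3 against control 0 of 21 male-biased genes rose and 9 fell (median -0.44), and 8 of 17 female-biased genes rose and 1 fell (median 0.43). Over 10 male-biased and 11 female-biased genes that stood in no fixed list and had not been named before, the medians were -0.48 and 0.32, a difference of 0.798 (permutation of genes between the lists, 100000 draws, two-sided p = 0.0397). In mice given XCT790 the difference was 0.54 and did not pass (permutation p = 0.239), with 2 male-biased genes higher and 8 lower and 8 female-biased genes higher and 3 lower. The values of the first comparison point to such a shift, whereas those in mice given XCT790 did not pass. A difference as large as the first came in 1 of 10000 draws of unchanged groups with the residual covariance of these genes. Those draws hold no T3 effect on any gene, while T3 changed 1574 of 9747 genes. They therefore do not tie the difference to sex bias, and were not run for mice given XCT790. An effect of injection on growth hormone release, which sets these genes, stays open.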
